A study of Mus musculus with 141 samples.

How the data were processed

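RNA was measured in single LT-HSC captured on a Fluidigm C1 chip, reverse transcribed and amplified in the chip with a SMARTer kit and made into libraries with Nextera XT, per the labels' protocols. The chemistry reads whole transcripts and carries no unique molecular identifiers, so a count is a read, not a molecule. Per the labels' protocols, each capture site was checked by microscopy for a single live cell. No doublet caller was run here. The values deposited by the authors are whole-number counts of reads per gene and cell, not normalized. Reads were handled with Trimmomatic 0.32, STAR 2.4.2a and HTSeq 0.6.1 on GRCm38.p4, per the submitters' processing notes, which give no role, order or annotation version. How reads shared by near-identical genes were counted is not given in the sources used here, so levels of families such as the H2 class I genes, the Gimap genes, the Ly6 genes and Ddx3y are uncertain. The library kits do not mark strand, so reads of a gene and of one overlapping it on the other strand cannot be told apart.

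The table held 45664 genes and 149 columns. Columns were matched to cells by their exact titles, which gave 141 cells, and 8 columns that matched no cell label were not used. No row lacked a gene name. Cells were grouped by the age in their labels, 3 months (76 cells) or 24 months (65 cells). The young cells came from 1 pool of 10 animals and the aged cells from 1 pool of 5. Cells of 1 pool are not replicates, so no test, standard error or p-value was computed. No label names a capture run, so age and capture run cannot be told apart. Young cells carry the number 1 in their titles and aged cells 1 or 14, and whether the number marks a run is not given in the sources used here. Young and aged cells of number 1 repeat the same site numbers in their titles. Read as capture sites, these show that the young and aged cells of number 1 cannot all come from 1 chip. Aged cells of numbers 1 and 14 have no site number in common, so they could share a chip. Values of the primary lists and of the secondary lists that stood apart are given for both numbers of the aged cells, a split of the lists chosen after the data were seen. All cells entered the main comparison. The highest correlation between any 2 cells across the ranked genes was 0.413, against a median of 0.296, so no cell was present in duplicate.

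Counts were divided by the cell total and expressed as CPM, then as log2(CPM + 1). A difference on this scale depends on the pseudocount and can differ from the log2 ratio of summed counts in either direction. For each gene the mean over cells of an age, the SD over cells and the difference aged minus young were computed. The share of cells with a read was given after thinning every cell to 2360000 reads, the 10th percentile of the totals rounded down, which left out 8 aged and 6 young cells, and without thinning. Shares have exact (Clopper-Pearson) 95% binomial intervals and summed counts exact Poisson 95% intervals. Where no cell had a read, or enough markers, the limit that 3 cells would set is given, and for the class II cells the upper end of the exact interval. Such a limit covers counting error only and bears on cells with reads, not on cells that express a gene. Cell totals of 84904 to 6609690 reads mean that 1 read stands for different CPM in different cells, which is why shares are compared at equal depth.

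Before the data were examined, 7 primary lists were fixed (platelet and megakaryocyte, genes reported as higher in aged HSC, interleukin-1 receptor and NF-kB response, HSC identity, G2/M phase, myeloid and lymphoid priming), with 16 secondary lists, 9 lists of cell type markers, the sort genes and the sex-linked genes. The secondary lists were S phase, cell cycle inhibitors and D cyclins, immediate early, heat shock and proteostasis, type I interferon response, antigen presentation, mitochondrially encoded, cytosolic ribosomal protein, oxidative phosphorylation, glycolysis, antioxidant, p53 target, autophagy and lysosome, chromatin regulator, TGF-beta and BMP, and adhesion genes. Genes with a read in at least 25% of the cells of 1 age and an accepted symbol were ranked, 5192 in all. Symbols that are clone or model numbers, pseudogenes or spike-ins were left out. The median difference of a list was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean level. That percentile describes these libraries and is not a p-value. The threshold of at least 5 reads of 3 or more markers for other cell types, and the 12 dendritic cell markers, were not among the choices fixed beforehand. A list is said to stand apart when it lies outside the central 95%.

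The genes named were fixed by rule: the 12 highest and 12 lowest differences among genes whose share at equal depth and summed CPM had the same sign of difference, the 4 members of each primary list and 2 members of each secondary list outside the central 95% with the largest absolute difference, and 14 genes always named (Itga2b, Vwf, Selp, Slamf1, Il1r1, Il1rap, Kit, Ly6a, Flt3, Cd48, Cdkn1c, Cdk6, Xist and Ddx3y). Lower members of the platelet and HSC identity lists were added after their values were seen. A gene that this rule selects is not reported here. Coordinates come from GENCODE M21 on GRCm38, in which 5052 of the 5192 symbols were found. Sdpr and Wapal were looked up under their current names.

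The ranking and the list percentiles were tested on simulated counts for the 5192 genes, with the real levels, spread and cell totals and 4 sets of 50 genes changed by known amounts. A log2 fold of 2 was recovered with the right sign in 94% of its 50 genes and a fold of -2 in 86%, with mean differences of 0.99 and -0.73. For folds of 1 and -1 the shares were 84% and 78%. In summed counts the folds of 2 and -2 gave mean log2 ratios of 1.97 and -1.89, farther from 0 than the mean differences. Most real genes ranked highest in aged cells had the opposite relation, so the simulated shares do not carry over to them. Of lists of 20 genes drawn from the genes with a fold of 2, -2, 1 and -1, 100%, 100%, 100% and 86% lay outside the central 95%, and 0% of 50 lists of unchanged genes. Each gene was simulated independently of the others, unlike genes of a real list that vary together between cells. The 0% therefore does not show how often such a list would stand apart through the sampling of cells.

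Alternatives were scran pooled size factors, totals without mitochondrially encoded genes, a pseudocount of 10, the log2 ratio of summed counts as CPM with 1 CPM added to each sum, thinned counts, cells within 3 median absolute deviations of their age, aged cells without title number 14, and a gene filter of 10% or none. For shares and genes per cell they were thinning to 3060000 reads, full depth, at least 5 reads, the same 3 deviations, and without title number 14. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with scran 1.30.0.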

Results

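Transcripts of single long-term haematopoietic stem cells (LT-HSC), the marrow cells that sustain blood formation over a lifetime, were counted in young and aged male C57BL/6 mice. Cells had been sorted as lineage-negative, Sca1-positive, cKit-positive, Flt3-negative, CD48-negative and CD150-positive. The 141 cells comprised 76 from mice of 3 months and 65 from mice of 24 months. Each age was 1 pool, of 10 young and 5 aged animals, so there was 1 sample per age and no replicate. No test between ages was therefore possible, and every difference describes these libraries. All 76 young cells and 58 of the 65 aged cells carried the number 1 in their titles and 7 aged cells the number 14, and what the number stands for is not given in the sources used here. Total counts per cell ran from 84904 to 6609690 reads, with medians of 3580980 in young cells, 3937700 in aged cells of number 1 and 1607340 in those of number 14. Mitochondrially encoded genes held a median of 3.13%, 1.98% and 7.86% of the reads of those 3 sets of cells. Only 3 of the 7 cells of number 14 reached the depth used for thinning. Values given for number 14 thus cannot be told apart from low library quality. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

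The age comparison asked how the transcripts of aged LT-HSC differ from those of young LT-HSC. The difference at the top of the ranking was in Egr1, a zinc-finger transcription factor induced within minutes of stimulation, whose mean log2(CPM + 1) was 10.15 (SD 2.61) in aged and 5.66 (SD 4.24) in young cells, 4.49 higher in aged cells. Next came Sdpr, now named Cavin2, a component of plasma-membrane caveolae, with a difference of 3.82. At equal depth a read of Sdpr was found in 66.7% (95% interval 52.9 to 78.6) of aged and 7.14% (95% interval 2.36 to 15.9) of young cells. Other early response genes followed, with Btg2, an antiproliferative factor, 3.35 higher, and the AP-1 subunits Jun and Fosb 3.21 and 3.09 higher in aged cells. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 3.31 higher and the clock gene Per1 3.15 higher. Gda, a guanine deaminase, was 3.30 higher, Rgs18, a regulator of G-protein signalling found in platelets, 3.22, Alcam, an adhesion molecule, 3.14, Vamp5, a vesicle protein, 3.08, and Nupr1, a stress-response regulator, 3.03.

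Summed over all cells of an age, Egr1 stood at 2455 (2449 to 2461) CPM in aged and 835 (832 to 839) in young cells, with exact Poisson 95% intervals in parentheses. For Sdpr the same values were 226 (225 to 228) and 1.84 (1.68 to 2.00). Egr1 lies on chromosome 18, 34859823 to 34864984, in GRCm38, and Sdpr on chromosome 1, 51289126 to 51302960. The gap in summed counts was smaller than the gap in mean log levels for 11 of the 12 genes, among them Egr1, at a log2 ratio (1 CPM added to each sum) of 1.55 and Rgs18, at 0.61. It was larger for Sdpr, at 6.33. Btg2 and Nupr1 were lower in the 7 cells of title number 14 than in young cells, with means of 4.76 against 6.97 and 1.81 against 2.83, and Tsc22d3 was at 4.90 against 5.02.

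**Figure D1:**
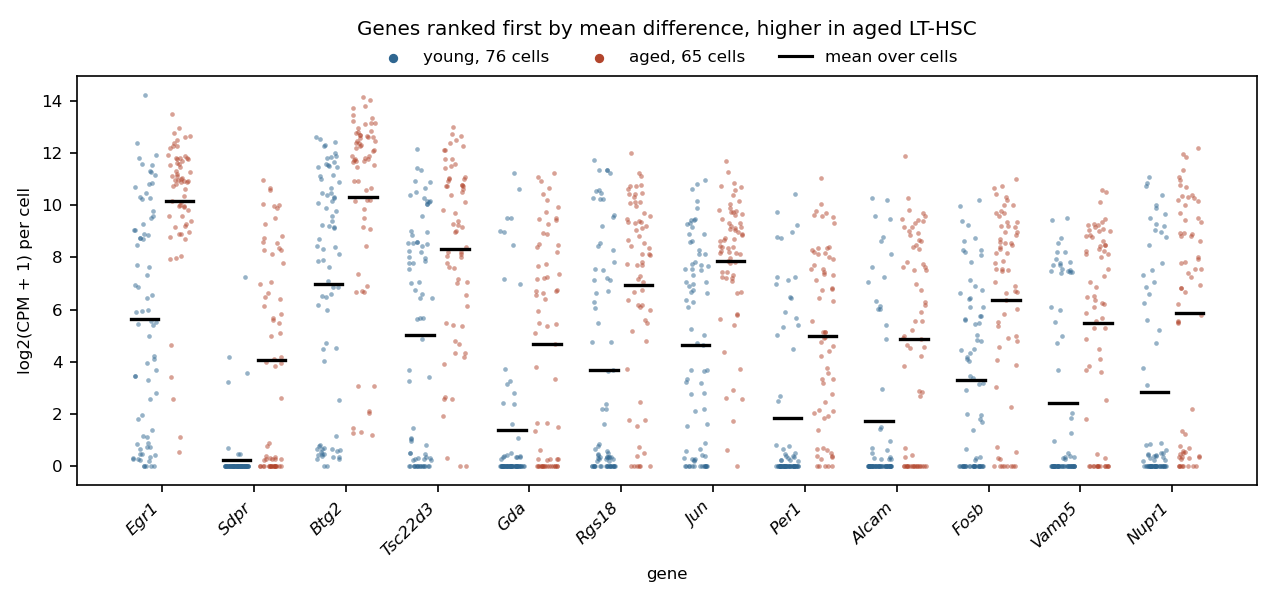
Levels per cell of the 12 genes ranked first among those higher in aged LT-HSC, as log2(CPM + 1). Each point is a cell, blue for the 76 young and red for the 65 aged cells, and black bars are means over cells. Egr1 averaged 10.15 in aged and 5.66 in young cells, and most young cells had no read of Sdpr.

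At the other end, Pmepa1, a membrane protein that dampens TGF-beta signalling, was lower in aged cells by the widest margin, with a mean of 1.93 (SD 3.05) in aged and 5.82 (SD 3.25) in young cells, a difference of -3.89. Cxcr4, the receptor through which CXCL12 retains stem cells in the marrow, differed by -3.58, and a read was found at equal depth in 38.6% (95% interval 26 to 52.4) of aged and 75.7% (95% interval 63.99 to 85.2) of young cells. Rgs2, a regulator of G-protein signalling, differed by -3.59. Lower in aged cells were also the transcription factor Mef2a (-2.76), Ski, a repressor of TGF-beta signalling (-2.64), and Vim, the intermediate filament vimentin (-2.60). The growth-arrest gene Gadd45a differed by -2.47. The chromatin-linked genes Ankrd11, Arid4b and Yaf2 differed by -2.67, -2.64 and -2.22, and the cohesin release factor gene Wapal, now Wapl, by -2.32. Zswim6 completed the 12 lowest with -2.24.

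In summed counts Cxcr4 stood at 10.1 (9.67 to 10.5) CPM in aged and 130.1 (129 to 131) in young cells. For Pmepa1 the values were 46.2 (45.3 to 47.1) and 228 (227 to 230.3). Cxcr4 lies on chromosome 1, 128588199 to 128592293, and Pmepa1 on chromosome 2, 173224458 to 173276533, both in GRCm38. Of the 12 genes, Rgs2, Ankrd11 and Ski had log2 ratios of summed counts less than 0.5 times as far from 0 as their mean differences, at -1.13, -1.15 and -1.25.

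**Figure D2:**
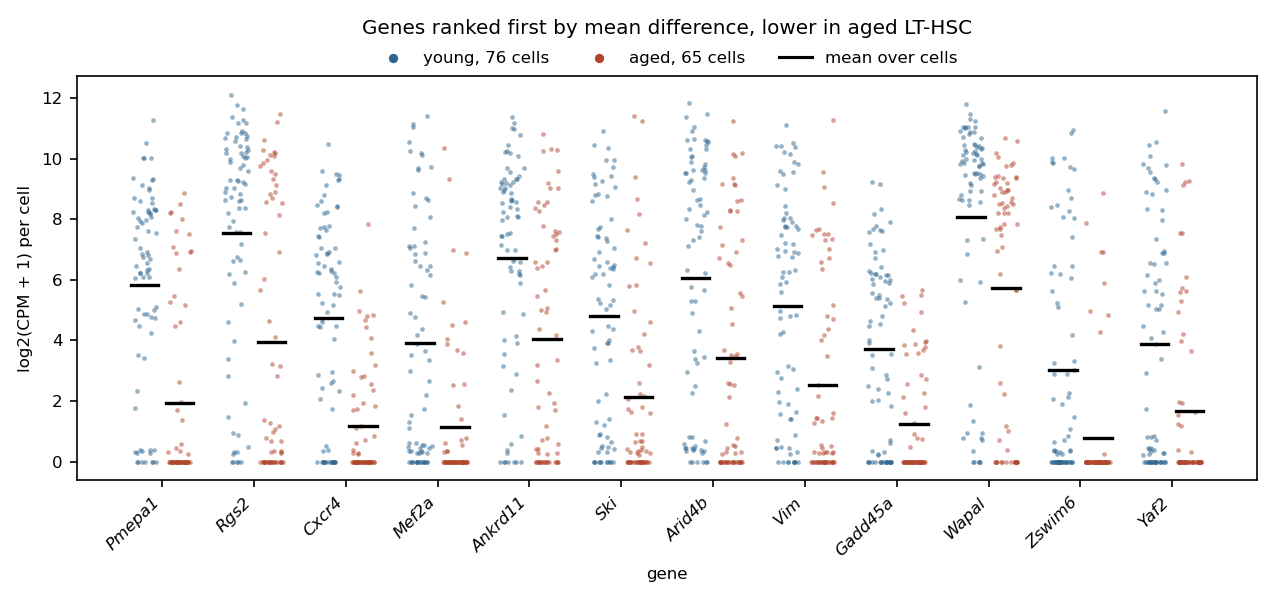
Levels per cell of the 12 genes ranked first among those lower in aged LT-HSC, as log2(CPM + 1), with points and bars as in the plot of genes higher in aged cells. Pmepa1 averaged 1.93 in aged and 5.82 in young cells.

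Platelet and megakaryocyte genes were higher in aged LT-HSC. Of the 18 list members with enough reads, 14 were higher and 4 lower, and the list median was 0.92 above young cells. Sdpr led, followed by Bin2 (2.78), by the integrin subunit gene Itgb3 (2.22) and by Selp, or P-selectin (2.06). Bin2 was common in young cells too, with a read in 68.6% of them at equal depth. The lower members were the thrombin receptor gene F2r (-1.59), Pf4, which encodes platelet factor 4 (-0.59), Pdgfb (-0.47) and Cd9 (-0.034). Pf4 was found at equal depth in 10.5% of aged and 20% of young cells. At equal depth Selp was detected in 40.4% (95% interval 27.6 to 54.2) of aged and 4.29% (95% interval 0.893 to 12.02) of young cells. Vwf, the clotting factor that marks platelet-biased stem cells, averaged 2.72 (SD 3.61) in aged and 1.29 (SD 2.99) in young cells and was found in 54.4% (95% interval 40.7 to 67.6) and 28.6% (95% interval 18.4 to 40.6) of them at equal depth. Without thinning the shares were 50.8% and 38.2%, and the summed counts of Vwf were close, at 122 and 107 CPM. Itga2b, which encodes CD41, was nearly level in mean log level, with a difference of 0.080. At equal depth it was found in 11 of 57 aged cells (19.3%, 95% interval 10.05 to 31.9) and 10 of 70 young cells (14.3%, 95% interval 7.07 to 24.7). Its summed counts were higher in aged cells, at 11.9 (11.4 to 12.3) against 7.21 (6.90 to 7.53) CPM. They rest on few cells, since 8 aged and 8 young cells had at least 5 reads of it without thinning. Reads of Itga2b and Vwf together occurred in 4 of 57 aged cells (7.02%, 95% interval 1.95 to 17) and 4 of 70 young cells (5.71%, 95% interval 1.58 to 13.99) at equal depth, and in 5 of 65 and 7 of 76 without thinning. At least 3 list genes were detected in all 57 aged and all 70 young cells kept at equal depth, and in all 65 and all 76 without thinning.

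The platelet list median lay at percentile 99.99 of 10000 random lists of matched level, whose central 95% ran from -0.26 to 0.50, as a description of these libraries. Against young cells the median was 0.89 in aged cells of title number 1 and -0.23 in the 7 of number 14. It was 0.22 with no gene filter and 0.43 with a pseudocount of 10.

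Genes that earlier reports give as higher in aged HSC were higher here too, in 19 of 20 members, with a median difference of 1.52, above all 10000 random lists. The members farthest from 0 were Sdpr, Alcam, Nupr1 and Tgm2, a transglutaminase (2.63). Tgm2 was found at equal depth in 77.2% of aged and 40% of young cells. The list shares Selp, Vwf, Itgb3 and Sdpr with the platelet list, and its other 16 members had a median of 1.39. The platelet median without these shared genes was not computed. On the ageing list, aged cells of title number 1 and number 14 stood 1.59 and 0.92 above young cells. Counted per cell at equal depth, a median of 10 of the 36 list genes had at least 5 reads in aged cells and 4 in young cells. Cells with at least 5 such genes numbered 51 of 57 aged (89.5%, 95% interval 78.5 to 96.04) and 29 of 70 young (41.4%, 29.8 to 53.8), against 58 of 65 and 34 of 76 without thinning. This count per cell was chosen after the data were seen. The list median was 0.85 with a pseudocount of 10 and 0.66 with no gene filter.

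**Figure D3:**
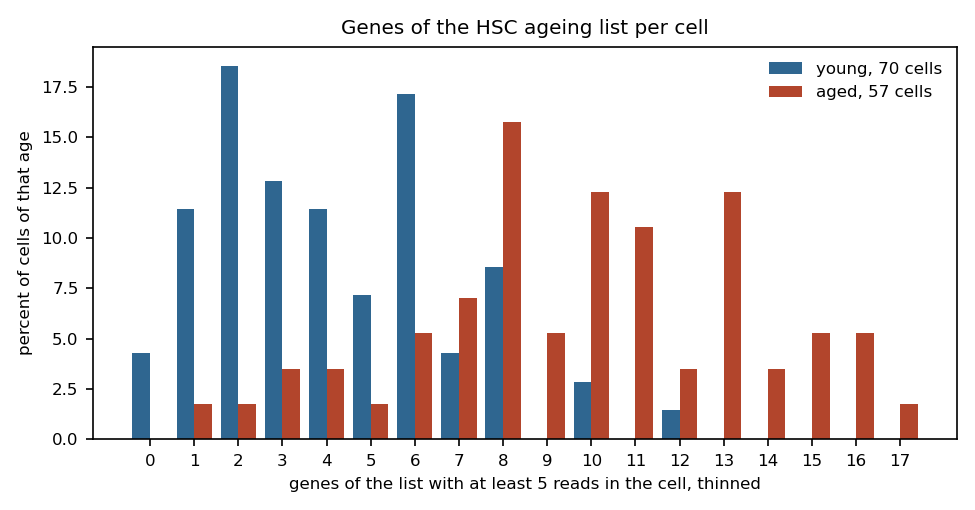
Share of the 57 aged (red) and 70 young (blue) cells, thinned to equal depth, against the number of the 36 genes of the HSC ageing list that had at least 5 reads in the cell. The medians are 10 genes in aged and 4 in young cells, and the ranges overlap, from 1 to 17 and from 0 to 12.

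Genes of HSC identity were mostly higher in aged cells, in 24 of 31 members. Mecom, a transcription factor needed for stem-cell maintenance, was 2.65 higher, with reads at equal depth in 96.5% of aged and 81.4% of young cells. Txnip, an inhibitor of thioredoxin, was 2.17 higher, and the homeobox gene Meis1 2.08 higher. Among the 7 lower members were Cd34 (-1.41), the transcription factor gene Hlf (-0.94) and the cyclin-dependent kinase inhibitor gene Cdkn1c (-0.51). The list median was 0.54, at percentile 99.7 of the random lists (central 95%, -0.22 to 0.40). Without the surface marker genes Ly6a, Kit and Cd34 it was 0.50, at percentile 99.8. With all members it was 0.67 in aged cells of title number 1 and 0.11 in those of number 14 against young cells, 0.33 in summed counts and 0.32 with a pseudocount of 10.

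Genes used for the sort are no finding. Kit and Ly6a, which encode cKit and Sca1, were found at equal depth in 91.2% and 59.6% of aged cells and in 82.9% and 42.9% of young cells, with differences of 0.98 and 1.67. The summed counts of Kit were close, at 391 and 399 CPM. Slamf1, which encodes CD150, differed by 0.33 and was found in 17.5% and 8.57%. Flt3, selected against, differed by -0.63, with reads in 3.51% and 12.9% of cells. Cd48 was seen in 0 of 65 aged cells, which allows a share of cells with a read of up to 4.62%, and in 1 of 76 young cells. Cd34, outside the gates, was lower in aged cells, at a difference of -1.41, with shares of 26.3% and 48.6% at equal depth and 27.7% and 52.6% without thinning. Ptprc, which encodes CD45, averaged 4.74 and 5.60. As a check of the male labels, the Y-linked gene Ddx3y was found at equal depth in 80.7% of aged and 82.9% of young cells, Eif2s3y in 36.8% and 47.1%, Kdm5d in 19.3% and 20%, and Uty in 49.1% and 48.6%. Xist, the X-inactivation RNA, had a read in 5 aged and 1 young cells and at least 5 reads in 2 aged and 0 young cells.

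Genes of the interleukin-1 receptor and NF-kB response went both ways and did not stand apart as a list. Of 17 members, 10 were higher and 7 lower in aged cells, with a median of 0.013 at percentile 24.1 (central 95%, -0.25 to 0.59). The adhesion molecule gene Icam1 was lower (-1.19), as were the NF-kB subunit gene Nfkb1 (-0.89) and Tnip1, an inhibitor of the pathway (-0.86), while Irak3, a brake on interleukin-1 receptor signalling, was higher (0.71). The receptor gene Il1r1 averaged 1.03 (SD 2.61) in aged and 0.56 (SD 2.21) in young cells, with reads at equal depth in 22.8% (95% interval 12.7 to 35.8) and 10% (95% interval 4.12 to 19.5) of them. Its summed counts went the other way, at 45.3 (44.4 to 46.1) and 49.6 (48.7 to 50.4) CPM. They rest on few cells, since only 9 of 65 aged and 4 of 76 young cells had at least 5 reads of it without thinning. The co-receptor gene Il1rap differed by -0.51, with reads in 7.02% (95% interval 1.95 to 17) of aged and 14.3% (95% interval 7.07 to 24.7) of young cells. Nfkb1 was level in summed counts, at a log2 ratio of 0.029. The list median was 0.22 and -0.040 for aged cells of title numbers 1 and 14 against young cells.

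S phase genes were lower in aged cells, while the G2/M list rested on few genes and its place depended on the gene filter. Of the S phase list, 11 of 14 members were lower and 3 higher, with a median of -0.50 at percentile 0.12 (central 95%, -0.27 to 0.57). Slbp, which binds the stem loop of histone messages, differed by -1.14, and Chaf1b, a histone chaperone subunit, went against the list at 1.16. Of the 32 G2/M genes, only 3 had enough reads: Top2a (-1.16), Cenpa (-0.87) and Mki67 (-0.37), with a median of -0.87 at percentile 0.375 (central 95%, -0.67 to 0.78). All 3 passed the gene filter in young cells only, so the filter itself favoured this direction. Top2a was found at equal depth in 19.3% of aged and 35.7% of young cells. Few cells of either age carried a G2/M programme: at least 5 of these genes had at least 5 reads in 1 of 57 aged and 5 of 70 young cells at equal depth, and in 2 of 65 and 5 of 76 without thinning. With the 10% gene filter 15 G2/M genes had a median of -0.18 at percentile 1.36, outside the random lists. With no gene filter the G2/M median was -0.042, inside the random lists at percentile 5.28. Against young cells the S phase median was -0.45 and -0.55 and the G2/M median -0.98 and -0.56 in aged cells of title numbers 1 and 14. Inhibitors of the cell cycle and D cyclins were split, 7 higher and 8 lower, with a median of -0.13 at percentile 16.6, which was 0.18 without the 7 cells of title number 14. Cdk6, a kinase that drives exit from quiescence, was level (-0.13).

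Neither priming list stood apart. Myeloid priming had 6 members higher and 3 lower in aged cells, with a median of 0.39 at percentile 75.7 (central 95%, -0.40 to 0.76). Prtn3, a neutrophil granule protease, was 2.85 higher and Anxa1 1.37 higher, while the chaperone gene Calr and Fcer1g, an Fc receptor chain, were lower (-1.08 and -0.64). The myeloid median changed sign to -0.033 with the 10% gene filter and -0.048 in summed counts, and was 0.31 and 0.048 in aged cells of title numbers 1 and 14 against young cells. Lymphoid priming had 10 members higher and 1 lower, with a median of 0.39 at percentile 77.2 (central 95%, -0.34 to 0.71). Mef2c and Bcl11a, transcription factors of lymphoid development, were 1.58 and 1.46 higher, and the GTPases Gimap1 and Gimap6 1.07 and 0.89. In the aged cells of title number 14 the lymphoid median was -0.62 against young cells, and 0.52 in those of number 1.

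Genes of antigen presentation were higher in aged cells, in 20 of 21 members, with a median of 1.03 above all 10000 random lists. Cd74, the invariant chain of MHC class II, averaged 4.82 (SD 4.20) in aged and 3.01 (SD 3.95) in young cells and was found at equal depth in 75.4% (95% interval 62.2 to 85.9) and 48.6% (95% interval 36.4 to 60.8) of them. The class I gene H2-T23 was 1.72 higher. The median was 1.03 and 0.50 above young cells in aged cells of title numbers 1 and 14, and 0.66 with a pseudocount of 10. Interferon response genes were higher in 17 of 21 members, with a median of 0.49 at percentile 98.5 (central 95%, -0.22 to 0.45). Ly6e, a membrane protein induced by interferon, was 1.65 higher and the signal transducer Stat2 1.23. With a pseudocount of 10 the interferon median was 0.25 and lay inside the random lists, at percentile 96.7. In aged cells of title numbers 1 and 14 it was 0.52 and 0.085 against young cells.

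Immediate early genes were higher in 22 of 31 members and lower in 9, with a median of 0.62 at percentile 99.8 (central 95%, -0.23 to 0.46), led by Egr1 and Btg2. Heat shock and proteostasis genes went the other way, with 23 of 27 lower and a median of -0.43 at percentile 0.055 (central 95%, -0.26 to 0.37). Pdia6, an oxidoreductase of the endoplasmic reticulum, differed by -1.81 and Herpud1, part of the degradation machinery there, by -1.27. In summed counts neither list stood apart, with medians of 0.20 at percentile 94.4 and -0.17 at percentile 20.6. Against young cells, the immediate early median was 0.74 in aged cells of title number 1 and -0.29 in those of number 14, and the heat shock median -0.37 and -1.54.

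The remaining lists lay inside the central 95% of their random lists. Nuclear genes of oxidative phosphorylation came closest, with 57 of 76 higher in aged cells and a median of 0.37 at percentile 96.4, followed by p53 targets and DNA damage genes, with 11 of 15 lower and a median of -0.23 at percentile 4.93. The p53 list fell outside with the 10% gene filter, at -0.14 and percentile 1.495, and with no filter, at -0.11 and percentile 0.475. Adhesion and niche homing genes had a median of 0.32 at percentile 87.04, with Alcam and Cxcr4 at opposite ends. Autophagy and lysosome genes stood at 0.23 (percentile 72.6), genes of TGF-beta and BMP signalling at 0.11 (49.9), glycolysis genes at 0.052 (44.7), antioxidant and metallothionein genes at 0.019 (30.8) and chromatin regulators at 0.0077 (24.2). Cytosolic ribosomal protein genes had a median of -0.11 at percentile 42.8, with 61 of 82 lower. Mitochondrially encoded genes had a median of 0.065 at percentile 73.4, and 1.73 in aged cells of title number 14 against -0.15 in those of number 1. The median difference over all 5192 genes ranked was 0.13.

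**Figure D4:**
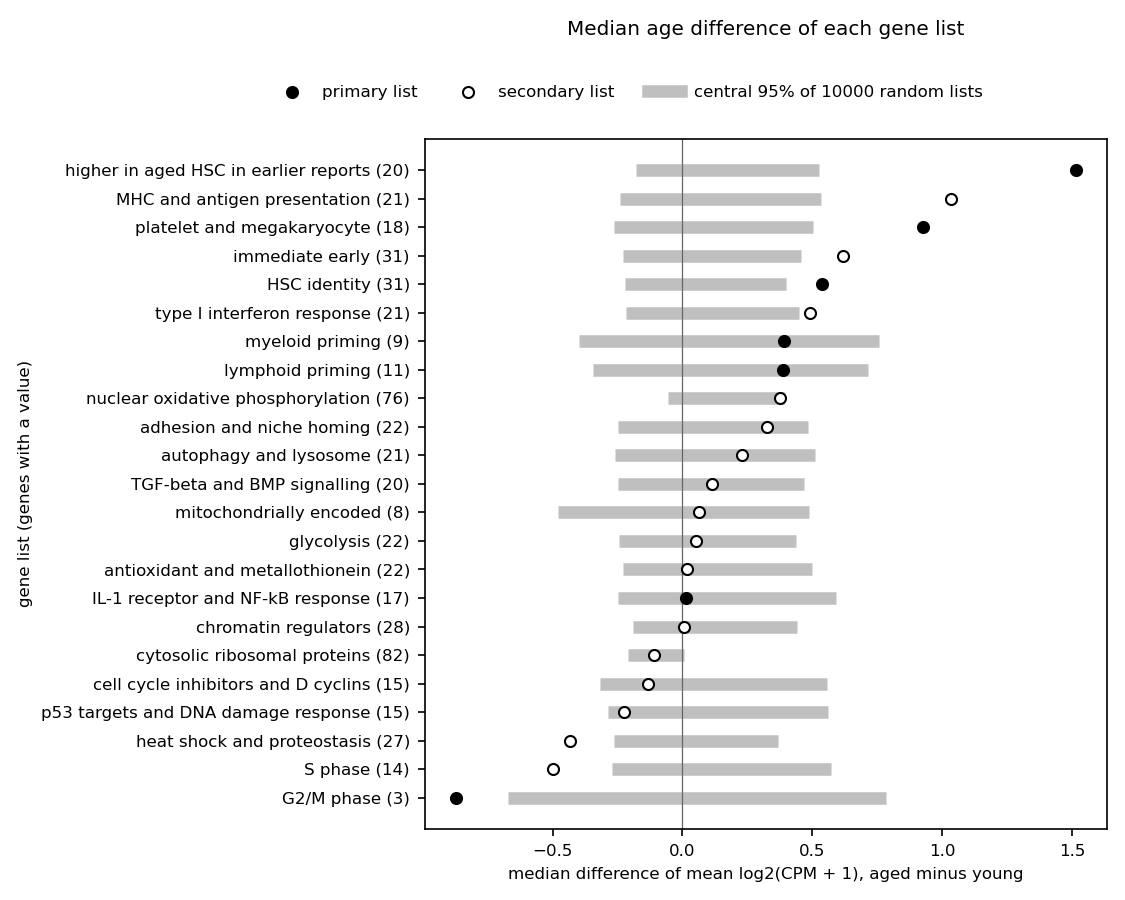
Median difference of mean log2(CPM + 1), aged minus young, of each gene list, with the number of genes behind it in parentheses. Grey bars are the central 95% of 10000 random lists of matched level, filled points primary and open points secondary lists. The ageing list stands highest at 1.52 and the G2/M list, of 3 genes, lowest at -0.87.

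Markers of other cell types were scarce, by a threshold that was not fixed beforehand. No cell of either age had at least 5 reads of 3 or more macrophage, neutrophil, erythroid, stromal and endothelial, or mast cell, basophil and eosinophil markers, which allows shares of up to 4.62% of aged and 3.95% of young cells. The same held for markers of unrelated tissues. Without thinning, B cell markers and T and NK cell markers each reached that level in 1 young and 0 aged cells. Mature megakaryocyte markers, which overlap with the platelet list, reached it in 7 of 57 aged (12.3%, 95% interval 5.08 to 23.7) and 3 of 70 young cells (4.29%, 0.893 to 12.02) at equal depth, and in 10.8% and 3.95% without thinning. Among these markers, Nrgn had at least 5 reads in 61.5% of aged and 32.9% of young cells, and Itgb3 in 44.6% and 17.1%, without thinning. Ppbp, Gp6 and Tubb1 reached 5 reads in no cell, so the count alone does not show mature megakaryocytes. At a single read and without thinning, 5 aged and 5 young cells had 3 or more macrophage markers, and 16 aged and 8 young cells had 3 or more mature megakaryocyte markers.

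Aged cells held more detected genes. At equal depth the median was 3472 genes with a read in 57 aged and 3195 in 70 young cells, and 2594 and 2116.5 genes with at least 5 reads. Without thinning the medians were 3716 and 3480.5 genes with a read. The share of detected genes that had only 1 to 4 reads was 28.7% in aged and 35.2% in young cells, as medians without thinning.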

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

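No paired analysis was possible because each age was 1 pool of animals and no label pairs a cell or animal of one age with one of the other, and leaving out a replicate was not possible for the same reason. All alternatives were chosen before the data were examined. Of the 9 lists outside the central 95%, G2/M rests on 3 genes whose direction the gene filter favoured and is not counted as kept. The other 8 stood apart on the same side with scran size factors, totals without mitochondrial genes, thinned counts, cells within 3 deviations, the 7 aged cells of title number 14 left out, and the 10% gene filter. The interferon list was lost with a pseudocount of 10, the heat shock and immediate early lists in summed counts, and the G2/M list with no gene filter. The p53 list joined with the 10% filter and with none. Sdpr and Selp, members of the platelet and ageing lists, also passed the gene filter in aged cells only. So did other members, among them Stat2 of the interferon list and H2-Eb1 of the antigen presentation list. Pf4 of the platelet list passed it in young cells only. With no filter the platelet and ageing lists still stood apart, at percentiles 98.5 and 100, and the interferon and antigen presentation lists at 98.8 and 100. No list that stood apart and no named gene with a difference of at least 1 took the opposite sign. Across settings, 156 of the list values moved by less than 1 SD of the random lists and 51 by more, and 425 of the gene values moved by at most 0.5 times the reported difference and 51 by more. The median over all genes ran from 0.0049 with no filter to 0.20 with cells within 3 deviations, against 0.13 as reported, and list percentiles are relative to it.

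List medians that moved by more than 1 SD of their random lists were, with a pseudocount of 10, platelet 0.43, ageing 0.85, HSC identity 0.32, G2/M -0.38, immediate early 0.31, heat shock -0.26, interferon 0.25, antigen presentation 0.66 and oxidative phosphorylation 0.18. In summed counts they were platelet 0.69, HSC identity 0.33, G2/M -2.16, myeloid -0.048, immediate early 0.20, heat shock -0.17, interferon 0.77, mitochondrial -0.41, oxidative phosphorylation 0.10 and antioxidant -0.18. With thinned counts they were ageing 1.74, HSC identity 0.71, immediate early 0.80, interferon 0.67, antioxidant 0.27, TGF-beta 0.38 and adhesion 0.54. Among cells within 3 deviations they were cell cycle inhibitor 0.37, immediate early 0.95, heat shock -0.23, oxidative phosphorylation 0.49, glycolysis 0.40, antioxidant 0.28 and adhesion 0.55. Without title number 14 they were cell cycle inhibitor 0.18 and glycolysis 0.24. With the 10% gene filter they were platelet 0.55, ageing 1.21, G2/M -0.18, myeloid -0.033, cell cycle inhibitor 0.19 and antigen presentation 0.80, and with no filter platelet 0.22, ageing 0.66, G2/M -0.042, myeloid -0.034, lymphoid 0.030, S phase -0.20, cell cycle inhibitor 0.21, interferon 0.26, antigen presentation 0.77 and adhesion 0.10. For all these settings the cause was not tested. Counting only at least 5 reads, Vwf was found in 14.3% of young cells and Itga2b with Vwf in 0% of 70, which allows a share of up to 4.29%. The other 34 values of shares stayed within their 95% intervals, and the gap in genes per cell ran from 236 to 478 genes, against 277 as reported. Depth limits how many genes are seen, with medians of 3472 genes in aged and 3195 in young cells at equal depth and 3716 and 3480.5 without thinning.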

Other observations

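The tests of read depth, of heat shock genes and of capture run for the immediate early genes, and of B cells and macrophages for the MHC class II genes, were chosen after the results were seen, as were the genes of the next paragraph and the definition of a class II cell. The tests of dendritic cells, of depth for class II genes and of low counts were chosen before their results were seen, but the minimums of reads for low counts were not in the prediction.

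Of the 15 markers of T and NK cells, Klrb1c and Nkg7 were picked out after the data were seen, and their shares differed in opposite directions. Klrb1c, which encodes the surface receptor NK1.1, had a read at equal depth in 17 of 57 aged cells (29.8%, exact 95% interval 18.4 to 43.4) and in 0 of 70 young cells, which allows a share of up to 4.29%. Without thinning it had a read in 18 of 65 aged and 0 of 76 young cells, and at least 5 reads in 13 of the aged cells. Nkg7, a granule membrane protein of cytotoxic cells, had a read in 7.02% of aged (1.95 to 17) and 21.4% of young cells (12.5 to 32.9) at equal depth, with overlapping intervals, and in 7.69% and 23.7% without thinning. No aged cell had at least 5 reads of 3 or more T and NK cell markers. The lipid carrier gene Apoe, listed as a macrophage marker, had at least 5 reads in 73.7% of aged and 44.3% of young cells at equal depth (69.2% and 47.4% without thinning), while no cell had 3 or more macrophage markers at that level.

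Immediate early genes were higher in aged cells while the heat shock and proteostasis list was lower. Read depth would have put the immediate early list inside its random lists once cells were thinned. The thinned median was 0.80, above their upper end of 0.46. Median total reads differed little between the ages to begin with, so this test could hardly have come out otherwise. Handling stress that raises both lists would have put the heat shock and proteostasis list above its random lists. Its median was -0.43, below their lower end of -0.26, although neither list stood apart in summed counts, at 0.20 and -0.17. That list also holds endoplasmic reticulum genes such as Pdia6 and Herpud1, so its median does not show that heat shock genes alone fell. The test therefore cannot decide on handling stress that raises heat shock genes alone. Capture runs that differ between the ages cannot be told apart from age. No label says whether the title number, which is 1 for all young cells too, marks a run. The 7 aged cells of number 14 had an immediate early median of -0.29 against young cells, where the 58 of number 1 had 0.74. Library quality moved with the number, at medians of 7.86% and 1.98% mitochondrial reads. Only 3 of the 7 were deep enough to thin. In them 25, 20 and 19 immediate early genes had at least 5 reads, against medians of 20 in the 57 aged and 16.5 in the 70 young cells at equal depth. Over all genes, 2389, 2925 and 2607 had at least 5 reads in these 3 cells, against medians of 2594 in aged and 2116.5 in young cells. The immediate early counts thus cannot be told apart from the number of genes detected per cell. The value of -0.29 therefore cannot be assigned to a run. A dissociation or sorting difference between runs, and age itself, both stay open, and age was not tested.

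MHC class II genes were higher in aged cells, with a median difference of 1.70 over Cd74, H2-Aa, H2-Ab1 and H2-Eb1, and at least 5 reads of the first 3 were found in 14 of 57 aged (24.6%, 14.1 to 37.8) and 7 of 70 young cells (10%, 4.12 to 19.5) at equal depth, and in 14 of 65 and 8 of 76 without thinning. B cells, macrophages or dendritic cells in the sort would carry their own markers, but 0 of the 22 class II cells had at least 5 reads of 3 or more markers of any of these types. The upper exact 95% limit was 15.4% for B cells, 15.4% for macrophages and 15.4% for dendritic cells. This covers only those 22 cells, while Cd74 alone had at least 5 reads in 39 of 65 aged and 29 of 76 young cells without thinning. The most frequent markers were Apoe in 10 and Fscn1 in 5 of the 22 cells, followed by Cd79b, Vcam1, Slc40a1 and Lgmn in 2 each. Depth was argued against by total reads that differed little, at medians of 3716540 in aged and 3580980 in young cells. The thinned median was 2.06, over the 57 aged and 70 young cells deep enough. With depths so close, thinning could hardly have lowered it, and thinning does not equalize the genes detected per cell. Age stays open as a hypothesis, untested, and cannot be told apart from the capture run.

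Reads passed between cells processed together are a candidate source of counts of 1 to 4. For genes with at least 95% of all reads in 1 cell, the prediction put such counts at least 2 times as often in cells of the same age as in the other age if so, and at most 1.5 times if not. The ratio was 1.37 for genes of an aged source cell (0.392% against 0.287%, 95% interval of the ratio 1.22 to 1.53) and 2.09 for those of a young source cell (0.413% against 0.198%, 95% interval of the ratio 1.87 to 2.33). The aged ratio met the bound against passed reads and the young ratio the bound for them, but both intervals, for counting error only, cross the bound, so passed reads cannot be told apart from faint expression shared by cells of 1 age or from age, both untested. The first run had added a minimum of 2000 reads that the prediction lacks and gave 2.27 and 2.86. Both ratios lie above the bound of 2, but the interval of the aged ratio, 1.87 to 2.77, crosses it. With minimums of 100, 500, 1000 and 5000, tried afterwards, the aged ratio was 1.38, 1.59, 1.85 and 2.43 and the young ratio 2.12, 2.42, 2.70 and 3.24.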
